A study of Caenorhabditis elegans with 6 samples.

How the data were processed

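Whole-body RNA of L4 hermaphrodites was extracted with TRIzol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols, which do not state that the libraries keep strand. Samples were grouped by the genotype in their labels, 3 wild type and 3 glna knockout. The submitters' processing notes name CASAVA 1.8, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.20.0 and the build WBcel235, without roles or order. Without strand, reads of overlapping and antisense genes cannot be told apart, and near-identical copies can share reads.

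The deposited table lists 21507 genes. Per the file headers and values, its signal columns are the authors' normalized counts, read counts divided by 1 size factor per library. The deposited log2 fold changes are of knockout over wild type, and the deposited p-values and adjusted p-values are those of the authors' comparison, with 6267 adjusted values at exactly 1. Group means and gene lengths, also deposited, were not tested. Dividing by each column's step gave whole reads for 100% of values (tolerance 0.01 read). In wild type replicate 1 the step is so near to 1 that it could be mistaken for rounding, but its values are multiples of the step and are not whole themselves. Recovered reads per library were between 18443661 and 19861540. At this depth the spread between replicates exceeded counting noise, with a chi-square per degree of freedom of 17.8 to 124 between replicates, so no library was a copy of another.

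Symbols came from the Ensembl 115 annotation and RefSeq locus tags and were matched for 21059 IDs. Coordinates are those of the deposited table. Gene IDs stand for genes that share a symbol, among them the 2 named *clec-209*.

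Designs, lists and the rule for named genes were fixed before the data were examined. As planned for normalized values, limma 3.58.1 in R 4.3.3 (trend, empirical Bayes) was fitted to log2(normalized count + 1) for the 15169 genes with a mean of at least 10 over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Camera tested 20 gene lists and 6 marker lists with a preset correlation of 0.01, adjusted over all 26, and counts of list members are given over all genes tested and adjusted over the list alone. Fisher's exact test compared chromosomes. Named genes were the glna genes; among called genes with non-overlapping groups, a mean of at least 50 and a symbol, the 6 largest rises and 6 largest falls; the 2 called members with the smallest adjusted p in lists with at least 3; and the 2 most abundant members of the sperm, glutamine and vitellogenin lists. Other genes named in the text as list members were chosen after their values were seen.

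Other settings chosen before the data were examined were quantile normalization, the authors' adjusted p, other filters and pseudocounts, a replicate block, leaving out each library, a fold change of at least 2, protein-coding genes, camera with an estimated correlation and fry. Fry tests whether the members of a list changed, without comparing them with other genes as camera does. Division of the deposited values by median-of-ratios factors was not run because they already carry such factors. Settings chosen after seeing the data were sample weights, a threshold of 0.1 and fits to the recovered reads. These fits were edgeR 4.0.16 with its default factors and with median-of-ratios factors, and DESeq2 1.42.0 with and without knockout replicate 1. DESeq2 on the recovered reads called the same 1236 genes as the authors' deposited table. In all, the number of changed genes was computed under 21 settings besides the main one.

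The tests were tried on counts simulated for 15169 genes of the knockout against wild type comparison, with 200 genes changed. limma found 59% of 2-fold and 100% of 4-fold changes, with 7 false calls among 166. DESeq2 found 77% and 100%, with 32 false calls among 209. The changed genes were drawn from those with a mean of at least 50, and counts were drawn independently for each gene and library. Shifts shared by many genes, or a library that stands apart, were not simulated. These shares therefore need not hold for the real libraries. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.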

Results

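RNA was sequenced from whole bodies of *Caenorhabditis elegans* hermaphrodites at L4, the last larval stage, in which hermaphrodites make sperm before switching to oocytes. The 6 libraries came from 3 samples of wild type (strain N2) and 3 samples of a glna knockout. The glna genes encode glutaminases, the enzymes that convert glutamine to glutamate and ammonia. Each library held between 18443661 and 19861540 reads assigned to genes, and 15169 of the 21507 listed genes passed the filter on low values. Correlations of log2 values across genes were 0.978 to 0.984 within wild type, 0.974 to 0.981 within the knockout and 0.940 to 0.982 between the genotypes. Knockout replicate 1 stood apart in composition. Ribosomal RNA genes took 3.58% of its reads, against 0.331% to 0.763% in the other 5 libraries, and its 10 most abundant genes took 13.65% of its reads, against 5.21% to 6.60%. Nothing in the labels states that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

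The first comparison asked what the glutaminase genes themselves showed in the knockout. *glna-2* (DH11.1, chromosome II, 8008619 to 8011630, plus strand, WBcel235) fell 8.07-fold, from 458 ± 56.3 normalized counts in wild type to 57.6 ± 17.6 in the knockout (SD, n = 3 each). *glna-3* (F30F8.2, chromosome I, 7826441 to 7831629, minus strand) fell 5.74-fold, from 689 ± 64.8 to 125 ± 46.6 normalized counts. *glna-1* (C09F9.3, chromosome II, 14721349 to 14728049, minus strand) averaged 264 ± 7.88 normalized counts in wild type and 156 ± 29.8 in the knockout. All 3 knockout values lay below all 3 wild-type values for each of these genes. In limma, the log2 fold changes were -3.01 (SE 0.25, adjusted p = 0.0222) for *glna-2* and -2.52 (SE 0.25, adjusted p = 0.0290) for *glna-3*. *glna-1* did not pass (log2 fold change -0.78, SE 0.17, limma adjusted p = 0.0762), while its adjusted p in the authors' deposited table was 0.00742. Adjusted over the list alone, all 3 genes were lower. The labels do not say which glna genes were knocked out, and reads remained at all 3 genes. Both calls were lost in limma without wild type replicate 1 (adjusted p = 0.0951 for both), 2 (0.115) or 3 (0.0530), and without knockout replicate 3 (0.0659 for *glna-2* and 0.0874 for *glna-3*).

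**Figure D1:**
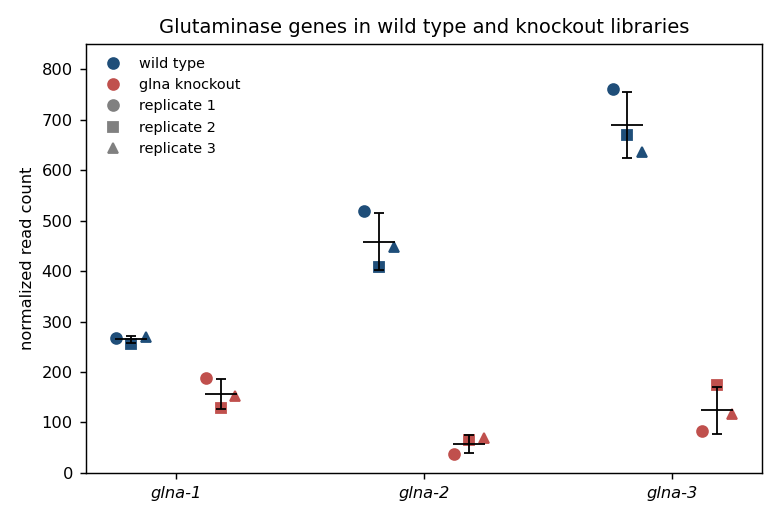
Normalized read counts (vertical axis) of the glutaminase genes in each library, with wild type in blue, the glna knockout in red, marker shape giving the replicate, and black bars giving the mean and SD of 3 libraries. *glna-2* averaged 458 in wild type and 57.6 in the knockout, *glna-3* 689 and 125, and *glna-1* 264 and 156.

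Beyond the glutaminase genes, the largest rises among genes chosen by the fixed rule included C-type lectin, transporter and channel genes. Y19D10A.9 (chromosome V, 2351676 to 2352932), a C-type lectin gene, rose from 31.4 ± 28.5 to 1077 ± 280 normalized counts (SD, n = 3 each), and F56A4.2 (chromosome V, 2459637 to 2460893) rose from 165 ± 33.2 to 839 ± 321. Both carry the symbol *clec-209* in the annotations used, so how reads were divided between them is uncertain; their sequences were not compared here. *ent-5*, of the equilibrative nucleoside transporter family, rose 5.99-fold, *spig-15* 3.26-fold, and *del-6*, of the degenerin sodium channel family, 2.98-fold, while *fipr-1* rose from 206 ± 44.4 to 628 ± 192. The rule takes only genes called by limma, with a symbol and a mean of at least 50. The largest falls it chose were in *glna-2*, *glna-3*, *fbxa-193* (7.24-fold), which is annotated as a pseudogene, *idpa-3* (4.25-fold), the aspartyl protease gene *asp-17* (4.21-fold) and *grsp-1* (4.08-fold). Some genes outside the rule moved further in the authors' deposited table. Examples, named after their values were seen, are *gtnt-7* (log2 fold change -5.24, authors' adjusted p = 5.4e-07) and *skr-7* (6.92, authors' adjusted p = 5.4e-04).

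Across the 15169 tested genes, limma called 54 genes at an adjusted p under 0.05, of which 32 were higher and 22 lower in the knockout. All 54 had groups that did not overlap. Among all tested genes 4631 (30.5%) had such groups, against 10% by chance for 3 against 3, and 3434 had an unadjusted p under 0.05. The calls lay close to the threshold: 35 of the 54 had an adjusted p of at least 0.049, and the smallest was 0.0222. The same threshold was passed by 1236 genes in the authors' deposited table (608 higher, 628 lower), and all 54 were among them. edgeR on the recovered reads called 19 genes (11 higher, 8 lower), all among the 54. The limma count was 0 without wild type replicate 1, 0 without wild type replicate 2, 1 without wild type replicate 3, 246 without knockout replicate 2 and 0 without knockout replicate 3, with 2810, 2022, 2490, 4065 and 3266 genes at an unadjusted p under 0.05. Without knockout replicate 1 it was 36, of which 6 were higher and 30 lower, and 17 of these were among the 54.

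**Figure D2:**
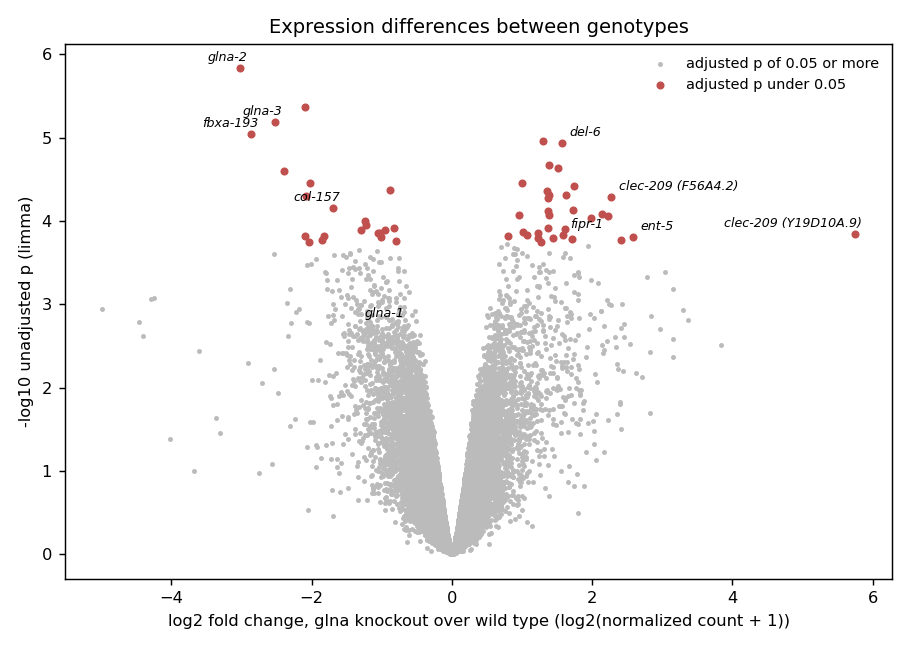
Each point is a tested gene, placed by its log2 fold change of the knockout over wild type on the log2(normalized count + 1) scale (horizontal axis) and by the negative log10 of its unadjusted limma p (vertical axis), with the 54 called genes in red. *glna-2*, at a log2 fold change of -3.01, has the smallest p, and Y19D10A.9, at 5.74, lies farthest to the right.

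The median of oocyte genes was higher in each knockout library than in any wild-type library, most of all in knockout replicate 1. All 38 measured oocyte and eggshell genes had positive log2 fold changes, with a median of 0.87, which was 0.50 without knockout replicate 1. None was called by limma over all genes tested, 28 had an unadjusted p under 0.05, 17 were higher in the authors' deposited table, and 27 were higher when adjusted over the list alone. These 27 included *meg-1*, a germ plasm gene (98.4 ± 64.2 normalized counts in wild type and 554 ± 405 in the knockout), *oma-2*, which acts in oocyte maturation (470 ± 200 and 1425 ± 908), and *rme-2*, the yolk receptor (1555 ± 489 and 3832 ± 2561; SD, n = 3 each). The list medians relative to the wild-type mean were 1.49, 0.48 and 0.57 in knockout replicates 1, 2 and 3 and 0.42, -0.30 and -0.13 in wild type replicates 1, 2 and 3, so that wild type replicate 1 lay close to knockout replicates 2 and 3. Camera placed the list above other genes with its preset correlation of 0.01 (adjusted p = 1.3e-10), but not with the estimated correlation of 0.87 (adjusted p = 0.783). The estimate was also 0.95 for vitellogenins, 0.79 for major sperm proteins, 0.65 for ribosomal proteins and 0.24 for collagens, but -0.31 for the glutaminase genes. Where the estimate is far above the preset, camera's adjusted p with the preset may be too small. The count adjusted over the list alone was 0 without knockout replicate 1, 0 without wild type replicate 2 and 0 without wild type replicate 3. It was 34 without wild type replicate 1, 33 without knockout replicate 2 and 31 without knockout replicate 3. In limma every fit that left out a library called 0 members over all genes.

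The 6 vitellogenin genes, which encode yolk proteins, had a median log2 fold change of 1.19, which was 0.47 without knockout replicate 1. The medians were 2.61, 0.78 and 0.17 in knockout replicates 1, 2 and 3 and 0.18, -0.02 and -0.14 in wild type replicates 1, 2 and 3, so that knockout replicate 3 lay within the range of wild type. *vit-6* averaged 129949 ± 19584 normalized counts in wild type and 347530 ± 230214 in the knockout, and *vit-2* 93087 ± 25606 and 287260 ± 202493 (SD, n = 3 each). None passed limma over all genes tested (adjusted p = 0.137 and 0.124 for these genes; 3 of 6 at an unadjusted p under 0.05; 0 in the authors' deposited table), and 3 were higher adjusted over the list alone, a count of 0 without any one of the wild-type libraries 1, 2 and 3 and of 6 without knockout replicate 3. Camera called the list (adjusted p = 0.0223; adjusted p = 0.783 with an estimated correlation), but not without knockout replicate 1 (0.0684) or wild type replicate 3 (0.0576).

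Sperm genes were compared because hermaphrodites make sperm at L4. Major sperm protein genes, which encode the cytoskeletal protein that moves nematode sperm, differed little: of 33 measured, 0 passed limma over all genes, 0 adjusted over the list alone, 5 had an unadjusted p under 0.05, and 1 was lower in the authors' deposited table. *msp-31* averaged 5777 ± 965 normalized counts in wild type and 4469 ± 689 in the knockout (limma adjusted p = 0.222), and *msp-40* 4956 ± 867 and 4226 ± 581 (0.420; SD, n = 3 each). Their medians did not separate the genotypes: -0.28, 0.14 and -0.24 in knockout replicates 1, 2 and 3, and 0.30, -0.19 and -0.10 in wild type replicates 1, 2 and 3. The median log2 fold change was -0.16 (-0.05 without knockout replicate 1 and -0.27 without knockout replicate 2), and camera gave an adjusted p of 0.0493 (adjusted p = 0.891 with an estimated correlation). That call was lost without knockout replicate 1 (0.293) or 3 (0.249), and without wild type replicate 1 the direction turned (0.977); with a replicate block it was also lost (0.0802).

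Among 76 other sperm genes, 66 had negative log2 fold changes, with a median of -0.37. None passed limma over all genes tested, 11 were lower when adjusted over the list alone, 30 had an unadjusted p under 0.05, and 14 were lower in the authors' deposited table. Of the 11, 8 were members of the *nspd* family of small nematode-specific peptides, a multigene family whose members may share reads. *nspd-7* averaged 961 ± 282 normalized counts in wild type and 183 ± 108 in the knockout. The other 3 were *fer-1*, needed for membrane fusion in sperm (715 ± 42.3 and 447 ± 27.4), *ssp-16* and *ssq-3*. The most abundant members, *ssq-2* and *ssq-4*, averaged 6208 ± 1278 and 6005 ± 1502 in wild type and 4760 ± 668 and 3706 ± 784 in the knockout (limma adjusted p = 0.240 and 0.121; SD, n = 3 each). Medians were -0.59, -0.19 and -0.37 in knockout replicates 1, 2 and 3 and 0.19, -0.11 and -0.11 in wild type replicates 1, 2 and 3. Camera placed the list below other genes (adjusted p = 4.0e-09; adjusted p = 0.783 with an estimated correlation). The count adjusted over the list alone was 26 without knockout replicate 2, 6 without knockout replicate 3 and 5 without wild type replicate 1, and over all genes tested 8 were lower without knockout replicate 2.

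Cuticle collagen genes differed mostly downward, in limma nearly all of them only when adjusted over the list alone. Of 142 measured, 74 were lower and 14 higher when adjusted over the list alone, 1 (*col-157*) was lower over all genes tested, and 67 were lower and 12 higher in the authors' deposited table. *col-157* fell 3.24-fold, from 7311 ± 1220 to 2314 ± 689 normalized counts, and *col-180*, which passed in limma only when adjusted over the list alone, averaged 13921 ± 2223 in wild type and 3902 ± 1903 in the knockout. Members that went the other way included *col-8*, at 2322 ± 895 and 8547 ± 2018, and *col-143*, at 373 ± 215 and 3295 ± 2376 (SD, n = 3 each). The median log2 fold change was -0.91, with medians of -1.44, -0.80 and -0.54 in knockout replicates 1, 2 and 3, and without knockout replicate 1 there were 69 lower and 12 higher genes over the list alone. Camera called the list (adjusted p = 1.3e-10; adjusted p = 0.783 with an estimated correlation). The number called over all genes was 9 lower without knockout replicate 1, 19 lower and 1 higher without knockout replicate 2, and 0 without any one of the other 4 libraries.

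Genes of the molting cycle had a median log2 fold change of -0.32 over 40 members (-0.20 without knockout replicate 1, -0.16 without 2 and -0.51 without 3). None passed limma over all genes tested (10 at an unadjusted p under 0.05), and adjusted over the list alone 5 were lower, *nas-38*, *bli-5*, *nas-36*, *wrt-4* and *ptr-23*, and *grd-3* was higher (1 higher and 5 lower in the authors' deposited table). Their medians did not separate the genotypes: -0.54, -0.69 and 0.09 in knockout replicates 1, 2 and 3, and -0.51, 0.29 and 0.27 in wild type replicates 1, 2 and 3. Camera called the list (adjusted p = 0.00623; adjusted p = 0.783 with an estimated correlation), but not without wild type replicate 2 (0.128), wild type replicate 3 (0.106) or knockout replicate 2 (0.133). Over all genes tested 1 was higher and 1 lower without knockout replicate 2. The number lower adjusted over the list alone was 2 without wild type replicate 1, 1 without wild type replicate 2, 2 without wild type replicate 3 and 9 without knockout replicate 3.

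**Figure D3:**
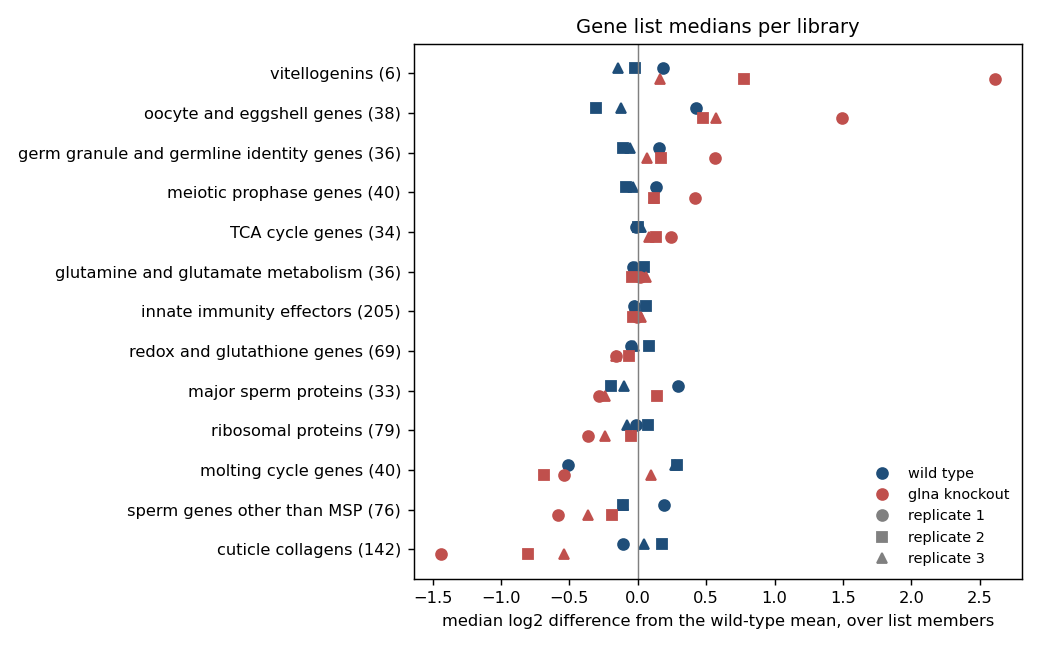
Median log2 difference from the wild-type mean over the measured members of 13 gene lists (horizontal axis; the number of measured members stands in parentheses), for each wild-type library in blue and each knockout library in red, with marker shape giving the replicate. Knockout replicate 1 lies at 1.49 for oocyte genes, 2.61 for vitellogenins and -1.44 for collagens, and wild type replicate 1 lies beside knockout replicates 1 and 2 for molting genes.

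Genes of glutamine and glutamate metabolism belong to the pathway in which glutaminase acts. Of 36 measured, 0 passed limma over all genes, 14 had an unadjusted p under 0.05, and the authors' deposited table has 4 higher and 3 lower. The list, fixed beforehand, leaves out *gln-4*, named here after its value was seen. It was lower in the authors' deposited table (log2 fold change -0.92, adjusted p = 0.0138) and was not called by limma over all genes. Adjusted over the list alone, *alh-13* and *pycr-1* were lower, at 3387 ± 612 and 1685 ± 249 normalized counts in wild type and 1557 ± 418 and 861 ± 259 in the knockout; both encode enzymes of the route from glutamate to proline. *gdh-1*, glutamate dehydrogenase, averaged 26424 ± 795 and 37208 ± 6862 (limma adjusted p = 0.140; 0.0440 in the authors' deposited table), and *gta-1*, a GABA transaminase, 8874 ± 88.1 and 9498 ± 357 (limma adjusted p = 0.601; SD, n = 3 each). The median log2 fold change was 0.01 and camera did not call the list (adjusted p = 0.869). Fry's test of change in either direction did call it (adjusted p = 0.0339), but that test makes no comparison with other genes. Of all 15169 tested genes, 3434 had an unadjusted p under 0.05. The count over the list alone was 1 without wild type replicate 1, 0 without wild type replicate 2, 0 without wild type replicate 3, 3 without knockout replicate 1, and 3 higher and 4 lower without knockout replicate 2.

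The tricarboxylic acid cycle list, which also holds genes outside the cycle itself such as *pck-2* and *pyc-1*, had a median log2 fold change of 0.14 over 34 members. *idh-1*, an isocitrate dehydrogenase gene, was higher adjusted over the list alone (6724 ± 885 and 11373 ± 1891 normalized counts). None passed over all genes in limma (9 at an unadjusted p under 0.05; 5 higher and 1 lower in the authors' deposited table), and the count over the list alone was 0 without any one wild-type library or knockout replicate 1, and 4 higher and 1 lower without knockout replicate 2. The members higher in the authors' deposited table were *idh-1*, *aco-1*, *ogdh-2*, *pck-2* and *pyc-1*, and the lower one was *sucl-2*. Camera called this list (adjusted p = 0.0147, or 0.783 with an estimated correlation). Since genes outside the cycle were among the higher members, this call does not show a rise of the cycle itself.

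Among 205 innate immunity effector genes, 5 rose and 0 fell over all genes tested in limma: Y19D10A.9, F56A4.2, *clec-204*, *fipr-1* and *fipr-2*. *fipr-2* rose 2.61-fold, from 672 ± 144 to 1755 ± 355 normalized counts (SD, n = 3 each). Adjusted over the list alone 12 were higher and 4 lower, the latter *spp-14*, *cnc-8*, *clec-52* and *spp-4*, and 24 were higher and 11 lower in the authors' deposited table. The list as a whole had a median log2 fold change of -0.01 while camera's direction was upward, and camera did not call it (adjusted p = 0.854). Fry's test of change in either direction, which makes no comparison with other genes, did call the list (adjusted p = 0.0125). The number called over all genes was 1 higher without knockout replicate 1, 1 higher without wild type replicate 3, 0 without wild type replicate 1, wild type replicate 2 or knockout replicate 3, and 5 higher and 3 lower without knockout replicate 2. Adjusted over the list alone, 6 were higher and 2 lower without wild type replicate 1, 5 and 3 without wild type replicate 2, and 8 and 5 without knockout replicate 1.

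Of 79 ribosomal protein genes, 75 had negative log2 fold changes, with a median log2 fold change of -0.23, or -0.14 without knockout replicate 1 (camera adjusted p = 8.1e-08; adjusted p = 0.783 with an estimated correlation). Medians were -0.37, -0.05 and -0.24 in knockout replicates 1, 2 and 3 and -0.01, 0.07 and -0.08 in wild type replicates 1, 2 and 3, so the genotypes overlapped. None passed limma over all genes (22 at an unadjusted p under 0.05; 7 lower in the authors' deposited table), and *rps-28* alone was lower adjusted over the list alone, a count that was 21 without knockout replicate 2, 4 without knockout replicate 1, and 0 without wild type replicate 1, wild type replicate 2 or knockout replicate 3. Over all genes tested, 4 were lower without knockout replicate 2. Meiotic prophase genes (40 measured, median 0.23, camera adjusted p = 0.00103) and germ granule and germline identity genes (36 measured, median 0.26, camera adjusted p = 7.2e-04) lay above other genes, each with an adjusted p = 0.783 with an estimated correlation. Without knockout replicate 1 the 2 medians were 0.12 and 0.13. The genotypes overlapped in both, with medians in replicates 1, 2 and 3 of 0.42, 0.12 and 0.12 in the knockout and 0.13, -0.09 and -0.04 in wild type for meiotic genes, and of 0.56, 0.17 and 0.07 and 0.15, -0.11 and -0.06 for germ granule genes. In both lists limma called 0 genes, over all genes and adjusted over the list alone, with 9 and 11 at an unadjusted p under 0.05 and 1 and 4 higher in the authors' deposited table. Without knockout replicate 3, 1 meiotic gene was higher, and 1 germ granule gene higher and 1 lower, adjusted over the list alone. Camera also called the glutaminase list itself (adjusted p = 6.3e-05; adjusted p = 0.299 with an estimated correlation).

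Camera did not call the lists of one-carbon and methionine cycle genes (adjusted p = 0.818), redox and glutathione genes (0.105), cytochrome P450 and UGT genes (0.492), fatty acid metabolism genes (0.543), heat shock and unfolded protein response genes (0.283), mitochondrially encoded genes (0.476) or core histones (0.912), though with the stricter filter, a mean of at least 50, it called the redox and glutathione list (0.0314). In the main fit limma called 0 members of each over all genes, with 6, 12, 25, 30, 6, 3 and 6 members at an unadjusted p under 0.05. In that order, the authors' deposited table has 2, 2, 8, 7, 0, 1 and 0 members higher and 2, 5, 2, 4, 2, 1 and 1 lower. Fry's test of change in either direction called the P450 and UGT, fatty acid and mitochondrially encoded lists (adjusted p = 0.0339 each). It makes no comparison with other genes, and 3434 of all 15169 tested genes had an unadjusted p under 0.05. These calls therefore do not set the lists apart from other genes. Adjusted over the list alone, *gst-10*, *ugt-6*, *hsp-16.41*, MTCE.31 and *his-35* were lower and MTCE.34 higher, each alone of its direction in its list, and 0 one-carbon or fatty acid genes passed. These counts depended on the libraries. Without knockout replicate 3, 3 one-carbon genes were higher and 1 lower adjusted over the list alone, and 3 fatty acid genes higher and 7 lower. Without knockout replicate 2, 2 fatty acid genes were higher and 4 lower adjusted over the list alone, and 6 P450 or UGT genes higher and 2 lower, while over all genes tested 3 fatty acid genes, 1 P450 or UGT gene and 1 redox gene were lower. Without wild type replicate 1, 1 fatty acid gene was lower adjusted over the list alone. The number lower adjusted over the list alone was 0 for heat shock genes without any one library, 0 for redox genes and for P450 or UGT genes without any one of the libraries other than knockout replicate 2, and 0 for histones without wild type replicate 2 or 3. Of the mitochondrially encoded genes, 1 was lower without knockout replicate 1, 1 higher without knockout replicate 2, and 0 passed without any one of the other 4 libraries.

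Markers of other cell types in a whole worm gave no list call in camera. Fry's test of change in either direction, which makes no comparison with other genes, called intestine markers (adjusted p = 0.0218) and spermatheca and sheath markers (0.0493). Camera's adjusted p was 0.818 for neurons, 0.516 for muscle, 0.869 for intestine, 0.818 for hypodermis and seam, 0.281 for spermatheca and sheath, and 0.606 for male-specific genes. limma called 0 of their members over all genes (0, 8, 7, 2, 4 and 1 at an unadjusted p under 0.05; 0, 3, 2, 1, 1 and 0 higher and 0, 0, 0, 0, 1 and 0 lower in the authors' deposited table). Adjusted over the list alone the intestine markers *mct-3* and *ttr-2* were higher, as was *tnt-3* on the spermatheca list. *tnt-3* is also on the muscle list, where it did not pass. Intestine markers then gave 0 without wild type replicate 2, 1 higher without wild type replicate 1, wild type replicate 3 or knockout replicate 3, 2 higher and 1 lower without knockout replicate 1, and 3 higher and 1 lower without knockout replicate 2, where 1 was also higher over all genes. Spermatheca markers gave 1 higher and 1 lower without wild type replicate 3 and 0 without wild type replicates 1 or 2 or knockout replicates 1 or 2. The median log2 fold change of spermatheca and sheath markers was 0.20, and their library medians did not overlap between the genotypes. These were 0.25, 0.13 and 0.10 in knockout replicates 1, 2 and 3 and -0.02, -0.05 and -0.01 in wild type replicates 1, 2 and 3. Muscle markers gave 2 higher and 3 lower without knockout replicate 2 and 2 higher without knockout replicate 3, and hypodermis markers 1 lower without knockout replicate 2. The median and camera's direction differed in sign for male-specific genes (median 0.34 over 3 measured genes, and 0.13, 0.71 and 0.18 without knockout replicates 1, 2 and 3), intestine markers (0.01) and, among the gene lists, core histones (0.07) and innate immunity effectors (-0.01).

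Genes that rose were concentrated on chromosome V. It held 16 of the 32 higher genes (50%) and 19.7% of tested genes, an odds ratio of 4.08 (Fisher's exact test, two-sided, adjusted p = 0.00143 over 12 tests). The test takes genes as independent. These 16 include both genes with the symbol *clec-209* and the close neighbours *fipr-1* and *fipr-2*, and *cat-4* and *del-6*. The adjusted p may therefore be too small. Chromosome I held 0 of the 32 higher genes and 2490 of the tested genes (adjusted p = 0.0392). The 22 lower genes passed on no chromosome, the smallest adjusted p being 0.241 on V. No test passed without any one of the wild-type libraries 1, 2 and 3 or knockout replicates 1 and 3, where limma called 36 genes or fewer, and 1 passed without knockout replicate 2.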

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

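Tests chosen after the data were seen are edgeR, DESeq2, sample weights and the 0.1 threshold. The 54 changed genes are 1 of many values: the other 21 settings gave 0 to 1236, 5 of them within 1.5 times. The count was 1236 by the authors' adjusted p and by DESeq2, 733 by DESeq2 without knockout replicate 1, 164 with no filter, 19 with the stricter filter, 19 with a pseudocount of 0.5, 19 by edgeR and 25 by edgeR with median-of-ratios factors, 320 with sample weights and 817 at an adjusted p under 0.1. Leaving out 1 library gave 0 to 246. The higher share also moved, from 32 of 54 to 17 of 25 with median-of-ratios factors and to 310 of 733 by DESeq2 without knockout replicate 1. The median log2 fold change of all tested genes was 0.01 under the deposited scaling, quantile normalization and edgeR. With a replicate block the count was 688, but whether the numbers pair the samples is not settled. The labels do not state that same-numbered samples shared a culture or day. Deviations of same-numbered libraries correlated at 0.20, -0.02 and 0.29. Replicates 1 and 3 matched their own number best, and replicate 2 did not. Of the glna genes, 0 to 2 were called without 1 library. Of the 11 called named genes other than glna, 5 were called with the stricter filter, 5 with a pseudocount of 0.5, 6 by edgeR under either scaling, and 0 to 10 without 1 library. Every named gene kept its direction in every setting that tested it. Camera called 11 of 20 gene lists, 9 to 12 under other scalings, filters and left-out libraries (redox and glutathione genes were added with the stricter filter, adjusted p = 0.0314), 0 with an estimated correlation and 1 (the glna genes) by fry's test of a shift in one direction, while fry's test of change in either direction called 8, and 2 of the 6 marker lists. Among the lists that fry's either-direction test did not call were oocyte genes (adjusted p = 0.112), other sperm genes (0.0591) and ribosomal protein genes (0.0803). The 2 chromosome tests became 0 with the stricter filter, 0 with a pseudocount of 0.5, 0 by edgeR, 1 by edgeR with median-of-ratios factors, 1 at a fold change of at least 2, 5 by DESeq2 and 5 without knockout replicate 1 in it, 6 with sample weights, 6 with the replicate block, and 0 to 1 without 1 library.

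A result is called reversed here where its direction turned, whether or not either value passed. That happened in 18 camera results, and the one that had passed beforehand was major sperm proteins without wild type replicate 1 (adjusted p = 0.977; 0.000769 to 0.977 over the 6 left-out libraries). The others, none past 0.05, included core histones by edgeR (0.878, and 0.893 with median-of-ratios factors), innate immunity effectors with the replicate block (0.984) and male-specific genes with no filter (0.794). The rest turned without 1 library, and over the 6 left-out libraries adjusted p was 0.774 to 0.956 for core histones, 0.445 to 0.977 for innate immunity effectors, 0.299 to 0.929 for male-specific genes, 0.774 to 0.977 for glutamine genes, 0.375 to 0.984 for hypodermis markers, 0.249 to 0.981 for one-carbon genes, 0.863 to 0.959 for intestine markers and 0.344 to 0.880 for neuron markers. Fewer samples lower the power of the fits that leave out a library; otherwise the cause was not tested.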

Other observations

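The tests of a shared axis, of variation among wild-type libraries, of males, of the collagen list and of the limma split count were chosen after the result, or values that largely determine it, had been seen. Among the genes that passed limma over all genes tested, and named here after their values were seen, *rhr-1*, of the Rh family of ammonium transporters, rose 1.94-fold, from 2944 ± 300 to 5731 ± 670 normalized counts (SD, n = 3 each; limma adjusted p = 0.0495), and *cat-4*, which encodes GTP cyclohydrolase, rose from 1277 ± 131 to 2554 ± 210 (limma adjusted p = 0.0422). *alh-10*, an aldehyde dehydrogenase gene, fell 1.78-fold and *cdd-1*, a cytidine deaminase gene, 2.04-fold (limma adjusted p = 0.0495 for both).

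In each knockout library the median of the oocyte list lay above, and those of the collagen and other sperm lists below, all 3 wild-type libraries, furthest in knockout replicate 1, while the yolk and major sperm protein lists overlapped between the genotypes. For collagens, the tables argue against that library as the whole cause, since the median log2 fold change was -0.66 (SE 0.16) without it; for oocyte genes the median of 0.50 without it passed the bound of 0.4 set beforehand, but by less than its SE of 0.22, a margin applied only after the value was seen, so this cannot be told apart. The planned test of a difference in developmental age along 1 axis, the correlation across genes of knockout 1 minus knockouts 2 and 3 with knockouts 2 and 3 minus wild type, gave r = 0.18, between its bounds of 0.2 and 0, and decided nothing; knockouts 2 and 3 enter both contrasts with opposite signs, which pushes r below 0. A second test, added because the first was undecided, used contrasts sharing no knockout library and gave a mean r of 0.33 (0.37 and 0.30). An axis along which the knockout libraries differ from wild type by unequal amounts would give such values. Knockout replicate 1 enters both correlations, and genes are not independent replicates. This second result does not replace the first, and it does not show that only 1 axis exists. The libraries also spread along a second principal component (18.54% of variance, against 51.25% on the first). On it, wild type replicate 1 and knockout replicates 1 and 2 lay at 31.6, 10.7 and 9.82. Wild type replicates 2 and 3 and knockout replicate 3 lay at -1.99, -14.3 and -35.8. A difference in age between the samples, an effect of the knockout on the pace of development, and both together stay open, as does a share of males, for which the male-specific genes (median 0.34, 3 of 9 measured, 0 of them with a mean of at least 50) decided nothing.

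The knockout libraries also differed among themselves. Whether wild-type libraries vary along the same axis was tested by correlating wild type 1 minus wild type 2 with knockout 1 minus knockouts 2 and 3 across genes; r was 0.16, between its bounds, so this stays open.

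The labels do not say which glna genes were knocked out, and variants linked to an altered locus were looked for only around *glna-2* and *glna-3*, the called ones, and not around *glna-1*: 0 of 844 tested genes within 1 Mb of them were called by limma (odds ratio 0, 95% interval up to 1.25, Fisher's exact p = 0.118), which argues against an excess of 3 times at those 2 loci. Of these genes 51 were called in the authors' deposited table, an odds ratio of 0.72.

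With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 54 genes by limma and 1236 by DESeq2, and in each case 1 of the 10 splits, the real one, gave as many. The highest of the others gave 45 and 255. Both came from the split of wild type replicate 1 and knockout replicates 1 and 2 against the other libraries. Every remaining split gave 0 by limma and at most 9 by DESeq2.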
